A study of Homo sapiens with 7 samples.

How the data were processed

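Pig liver RNA had been labelled as cRNA and hybridised to human U133 arrays (set A), per the labels. The deposited table held 1 linear intensity per probe set and array, for 7 arrays and 22283 probe sets, of which 68 were Affymetrix controls. The summary method, the scaling target and the software behind these intensities are not given in the sources used here. Per the labels, intensities under 100 were filtered by the authors, but at least 54.2% of the deposited values of each compared array lay under 100. Human probes read pig transcripts only where the sequences match, so a low value can mean a poor match as well as a scarce transcript, and levels of different genes were not compared. The 3' to 5' ratios of the control genes are compared only between arrays.

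Groups came from the letters in the sample titles, 3 arrays for A and 3 for C, and the direction of each difference is A over C because no label defines the letters. The replicate numbers in the titles are shared by no pair of samples. The seventh array entered no comparison, its values had 2 decimals and its 68 control probe sets were empty. No pair of the 6 arrays shared more than 2 identical values, and none was treated as a repeat of another.

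The trimmed means of the 6 arrays (2% trimmed at each end) differed by at most 1.04-fold, within the bound of 1.1 set in advance, so intensities were used as deposited. A pseudocount of 16 was added and log2 taken; fold changes are on this scale, which understates the change of dim probe sets. Probe sets with at least 100 on at least 3 of the 6 arrays were tested, 10017 in all, with the control probe sets left out. Some with all C values under 100, such as NUCB2, RPL36, ISG15, FABP1 and CYBB, passed this filter only through their A arrays. The test was lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The rule of the sample text, 2-fold or more at p under 0.05, was applied to unadjusted p from the same fit, since the labels name no test for it.

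Gene names came from the platform annotation of the arrays: 19071 probe sets had 1 symbol, 1043 had several and 2169 were unnamed. Of those with 1 symbol, 19059 were matched by Entrez ID to the current human RefSeq genes, and 0 symbols changed. No gene was named from a probe set with several symbols. The files name no genome build and hold no coordinates, so none are given. A gene was represented by its brightest tested probe set over the 6 arrays.

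Before the data were examined, 29 gene lists were fixed: methionine and folate cycle, ER stress, fatty acid and triglyceride synthesis, cholesterol, fatty acid oxidation, alcohol metabolism, drug metabolism, glutathione, acute phase, cytokines, interferon response, matrix and stellate cells, bile acids, urea cycle, glucose metabolism, respiratory chain, ribosomal proteins, proteasome, heat shock, cell cycle, apoptosis, DNA methylation, and markers of hepatocytes, macrophages, lymphocytes, neutrophils, endothelium, bile ducts and erythroid cells. Lists with at least 5 measured members, 27 of them, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry (statmod 1.5.0). Members were also adjusted over their own list alone, which was not in the design and does not correct for the number of lists. The design, the alternatives and the rule for naming genes were fixed with the lists. That rule took up to 10 genes per direction past the adjusted threshold and with no overlap between the groups. It filled up from the 2-fold rule, also with no overlap, in order of p. For each list it took the members past the threshold or, where there were none, the 2 with the smallest p, and it always took 26 genes of methionine, lipid, alcohol and stress metabolism. Of these, 1 is not reported here. Only 4 genes met it on the lower side. Other genes named (PDIA3, COX4I1, RPL22, RPS4X, HSD17B4, ABCB4 and CYP27A1, and the genes of the closing section outside the rule) were chosen after their values were seen. The control probe sets were examined outside that rule.

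The tests were run first on 20 simulated data sets with the means and residual spreads of the 10017 probe sets and 200 changed probe sets each. Of 2-fold changes, 89.3% passed the adjusted threshold and 50.7% the 2-fold rule; of 4-fold changes, 98.7% and 99.9% did. The mean number of false calls was 9.65 and 6.05. A shift of 0.3 added to the ribosomal list was called in 20 of 20 data sets, and in 17 with an estimated correlation, while unchanged lists were called 0.05 times per data set on average. Errors were drawn independently for each probe set, so the simulation does not cover genes that vary together. It also planted 200 true changes, which eases the Benjamini-Hochberg threshold, whereas the data gave 3 calls. Of the 33 probe sets that met the 2-fold rule in the data, only NUCB2 and RPL36 passed the adjusted threshold. The simulated detection shares may therefore not hold for these data.

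Alternatives were pseudocounts of 1 and 64, no filter, a filter on the mean, quantile, median and 75th percentile scaling, eBayes with a trend, array quality weights, probe sets without a family suffix only, each replicate left out in turn, and the mean of all probe sets of a gene. A filter of 200 was added after the data were seen. For the left-out replicates, the 100-unit filter was first applied to the remaining 5 arrays. After its counts were seen, the fit was changed to keep the probe sets tested on all 6 arrays, because NUCB2 and RPL36 were otherwise excluded by construction when an A array was left out, and both versions are reported. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.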

Results

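Pig liver RNA was measured on 7 Affymetrix Human Genome U133 arrays (set A), whose probe sets were designed for human transcripts, so each value is the signal of pig cRNA on human probes. The sample titles put 3 arrays under the letter A (A74, A63 and A72) and 3 under the letter C (C61, C64 and C75). The labels speak of ethanol feeding, folate deficiency and a control, but they tie no letter to a diet, so each direction is given as A over C. The remaining array has a title that joins the word control with the letters FDE, and it entered no comparison. Each of the 6 compared arrays gave values for 22283 probe sets. Array medians lay between 88.3 and 93.2 intensity units, and between 42.3% and 45.8% of the probe sets reached 100. The comparison tested 10017 probe sets, which stood for 6682 named genes, and 69.3% of those tested had a mean under 181 units, that is 2 times the median of 90.6 over the 6 arrays. Pearson's r between arrays, across the probe sets tested, lay between 0.834 (A63 and C64) and 0.943 (C61 and C64). The labels do not state that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

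The comparison of A with C asked which liver transcripts differed between the groups behind the letters. NUCB2, RPL36 and RPS19 rose in A, and 0 probe sets fell at the same threshold. NUCB2, which encodes the calcium-binding protein nucleobindin 2, averaged 234 ± 7.11 units in A (SD, n = 3) against 25.8 ± 13.8 in C (SD, n = 3), a log2 fold change of 2.63 (SE 0.20) with a limma adjusted p of 0.00273. Its C mean lay below the array medians of the B. subtilis control probe sets, 30.1 to 36.5 units, so the size of the rise is not fixed by the data: the log2 fold change was 3.25 with a pseudocount of 1 and 1.74 with 64. RPL36, a protein of the large ribosomal subunit, averaged 230.0 ± 3.67 units in A against 86.3 ± 0.794 in C, a log2 fold change of 1.27 (SE 0.08) with a limma adjusted p of 0.00145. Its C values lay under 100 and under the array medians, so it was tested only through its A arrays. Its log2 fold change lay between 0.97 and 1.40 over the alternatives. RPS19, a protein of the small ribosomal subunit, averaged 508 ± 9.41 units in A against 262 ± 28.2 in C, a log2 fold change of 0.92 (SE 0.10) with a limma adjusted p of 0.03675. The brighter RPS19 probe set differed less, with a log2 fold change of 0.44 (SE 0.11) that did not pass. At an unadjusted p under 0.05, limma gave 441 probe sets higher and 341 lower in A, 782 in all, where chance alone would give 500.8; without A74 the count was 1310, and without C64 it was 456, below that number. All 3 A arrays lay on 1 side of all 3 C arrays for 1324 probe sets, or 13.2% of those tested, where chance gives 10%. An exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.1, so the calls rest on limma's pooled variance. The count of 3 became 22 with array quality weights, 19 without A63 and 14 without C75, and it became 0 without A74 or A72 when the intensity filter was applied to the remaining 5 arrays. RPS19 passed in 12 of the 23 alternatives that tested it (limma adjusted p between 0.02385 and 0.189), and missed without A74 (0.117), A72 (0.145), C61 (0.0612) and C64 (0.0917).

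The rule in the sample text, a change of 2-fold or more at an unadjusted p under 0.05, took 33 probe sets, 23 higher and 10 lower in A. NUCB2 and RPL36 were among them, and the genes that follow did not pass the adjusted threshold. The interferon-induced genes IFITM3, IFITM1 and ISG15 were higher under this rule. The interferon response list, which holds ISG15 but no IFITM gene, did not pass, with 5 of 9 members higher (camera adjusted p 0.329). All 9 had a mean under 181 units, so the list says little about a wider response. IFITM3 averaged 1486 ± 260.4 units in A against 374 ± 251 in C (log2 fold change 2.16, SE 0.43), and IFITM1 averaged 353 ± 51.7 against 109 ± 45.9 (1.61, SE 0.23). ISG15, a ubiquitin-like protein induced by interferon, averaged 189 ± 32.1 against 71.6 ± 20.1 (1.24, SE 0.18). MANF, a secreted protein of the endoplasmic reticulum, averaged 463 ± 124 against 169 ± 43.9 (1.37, SE 0.23). The beta-tubulin genes TUBB, TUBB3 and TUBB4B had log2 fold changes of 1.31 (SE 0.24), 1.17 (SE 0.20) and 1.15 (SE 0.21). Their values ran in parallel: A74, A63 and A72 read 672, 382 and 784 units for TUBB, 419, 258 and 491 for TUBB3 and 693, 391 and 733 for TUBB4B. Whether the tubulin probe sets, or those of IFITM3 and IFITM1, read a shared pig signal was not tested. They may not be separate observations. Of the 3 TUBB probe sets tested, the 1 without a family suffix had a log2 fold change of -0.02. On the lower side, CYP3A43 averaged 1088 ± 505 units in A against 2638 ± 609 in C (log2 fold change -1.34, SE 0.31), and CYP3A4, a main drug-metabolising cytochrome P450 of human liver, averaged 132 ± 50.5 against 345 ± 53.5 at 1 of its 3 probe sets (-1.34, SE 0.24). SOCS2, an inhibitor of growth hormone signalling, averaged 125 ± 58.2 against 331 ± 94.1 (-1.35, SE 0.28), and the scaffold gene MPDZ averaged 94.6 ± 16.7 against 280.4 ± 143.9 (-1.31, SE 0.32). In 29 of the 33 probe sets, 23 higher and 6 lower, the A and C arrays did not overlap. With a pseudocount of 64 the rule took 21 probe sets, without C75 it took 56, and among probe sets without a family suffix it took 6, all higher in A. Single arrays decided some calls: without A63, the adjusted p from limma was 0.00306 for TUBB3, 0.00306 for TUBB4B and 0.00577 for TUBB, and without C75 it was 0.0062 for IFITM1 and 0.0309 for IFITM3. Over the alternatives, the adjusted p lay between 0.00306 and 0.366 for these tubulin genes, between 0.0062 and 0.237 for IFITM1 and between 0.0309 and 0.461 for IFITM3.

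**Figure D1:**
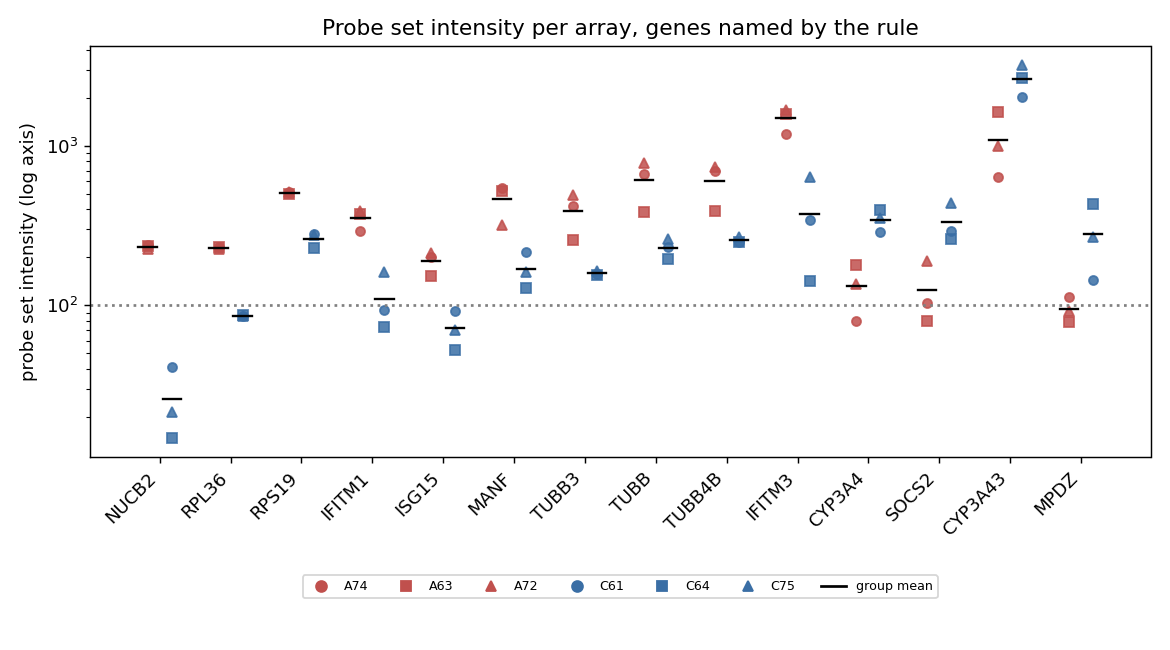
Intensity of each of the 14 genes named from the whole table, on a log axis, with red symbols for the 3 A arrays, blue symbols for the 3 C arrays and black lines for group means. The dotted line marks 100 units. NUCB2 lay between 225 and 239 on the A arrays and between 14.7 and 41.3 on the C arrays. The symbols of A and C do not overlap for any gene shown because the naming rule required it.

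Most cytosolic ribosomal protein genes were higher in A, but the list passed only with camera at the preset correlation, not with an estimated correlation or in the fry test. Of 32 measured members, 30 were higher and 2 lower, with a median log2 fold change of 0.32. The camera test with a preset correlation of 0.01 gave an adjusted p of 5.27e-16, but the adjusted p was 0.499 with an estimated correlation and 0.109 in the fry test. Adjusted over the list alone, 16 members were higher, while 0 of the brightest probe sets that stood for the members passed over all probe sets tested (RPS19 did at its dimmer probe set), and 21 were higher at an unadjusted limma p under 0.05. RPS9 averaged 907 ± 82.3 units in A against 603 ± 48.1 in C (log2 fold change 0.58, SE 0.11), and RPS23 averaged 306 ± 19.7 against 215 ± 7.57 (0.47, SE 0.09). RPL22 (-0.16, SE 0.14) and RPS4X (-0.01, SE 0.18) were the lower members. The list's mean deviation from each gene's average was 0.18 on A74, 0.07 on A63 and 0.24 on A72, against -0.10 on C61, -0.24 on C64 and -0.15 on C75.

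Genes of the mitochondrial respiratory chain were also mostly higher, by less. Of 28 measured members, 23 were higher, with a median log2 fold change of 0.11 (0.02 to 0.16 over the alternatives, the lowest without A74). Their mean deviation from each gene's average was 0.20 on A74, -0.0076 on A63 and 0.04 on A72. It was -0.02 on C61, -0.12 on C64 and -0.09 on C75, so A74 stood apart and A63 lay close to C61. The list passed only with camera at the preset correlation, with an adjusted p of 0.00144. The adjusted p was 0.684 with an estimated correlation and 0.399 in the fry test. The members adjusted over the list alone were 3, all higher and all subunits of cytochrome c oxidase. COX7C averaged 698 ± 91.6 units in A against 403 ± 38.1 in C (log2 fold change 0.77, SE 0.12), COX7A2 averaged 236 ± 20.9 against 151 ± 23.9 (0.60, SE 0.13), and COX4I1 had a log2 fold change of 0.42 (SE 0.09). In glucose metabolism, 12 of 16 measured members were lower, with a median log2 fold change of -0.15 (-0.17 to -0.09 over the alternatives). The list's mean deviation from each gene's average overlapped between the groups. It was -0.13 on A74, -0.09 on A63 and 0.0049 on A72, against 0.18 on C61, -0.0085 on C64 and 0.05 on C75. As a list these genes were lower with a camera adjusted p of 0.03687. The adjusted p was 0.499 with an estimated correlation and 0.166 in the fry test. FOXO1, a transcription factor that drives gluconeogenic genes, averaged 125 ± 7.57 units in A against 209.5 ± 48.4 in C (log2 fold change -0.65, SE 0.16) and was the 1 member adjusted over the list alone, although its second probe set had a log2 fold change of 0.09. Over all probe sets, FOXO1 passed without C75 (limma adjusted p 0.0498, between 0.0498 and 0.670 over the alternatives). PC, which encodes pyruvate carboxylase, averaged 244 ± 36.4 against 332 ± 50.7 (-0.42, SE 0.14). Without A74, the camera adjusted p was 0.359 for the respiratory chain and 0.352 for glucose metabolism. The glucose metabolism list also missed the threshold without A63 (adjusted p 0.110) and without C61 (adjusted p 0.170), and over the alternatives the adjusted p lay between 8.27e-07 and 0.684 for the respiratory chain and between 0.00763 and 0.779 for glucose metabolism.

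**Figure D2:**
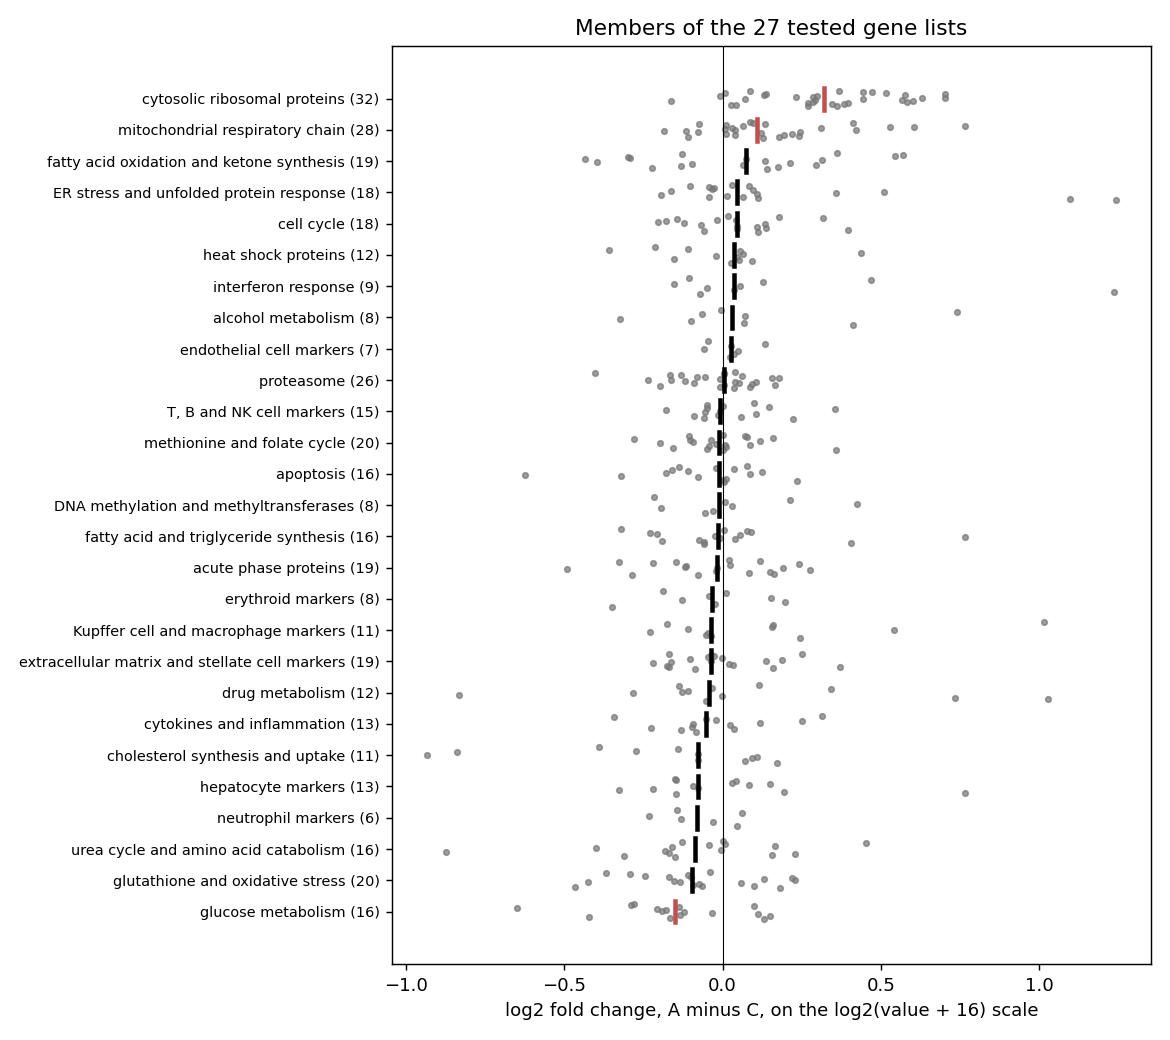
Log2 fold change, A minus C, of each measured member (grey points) of the 27 tested gene lists, on the scale of intensity plus a pseudocount of 16, with the number of measured members in brackets. Thick bars mark list medians, in red for the 3 lists past the camera threshold: ribosomal proteins at 0.32, respiratory chain at 0.11 and glucose metabolism at -0.15, with an adjusted p of 0.499, 0.684 and 0.499 at an estimated correlation.

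Among 18 measured genes of ER stress and the unfolded protein response, 11 were higher and 7 lower in A, with a median log2 fold change of 0.05 and a mean of 0.17. The list did not pass (camera adjusted p 0.287). CANX, HSPA5, HSP90B1 and PDIA3, chaperones and folding enzymes of the endoplasmic reticulum, were the members with an unadjusted limma p under 0.05, all higher. HSPA5 averaged 946 ± 412 units in A against 372 ± 109.7 in C (log2 fold change 1.24, SE 0.35), and HSP90B1 averaged 582 ± 367 against 233 ± 27.9 (2.14-fold, SE 0.35 in log2), with 1000 units on A74 and a log2 fold change of 0.63 without it; its dimmer probe set averaged 263 ± 90.8 against 109.6 ± 2.35. CANX averaged 637 ± 41.1 against 493 ± 40.4 (0.36, SE 0.10). None of these passed the adjusted threshold. The transcription factors ATF4 (0.06, SE 0.11) and DDIT3 (0.11, SE 0.09) did not pass, and XBP1 did not reach the intensity filter. With a filter of 200 in place of 100, chosen after the data were seen, the list's camera adjusted p was 0.0343, and over all alternatives it lay between 0.0343 and 0.779.

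Methionine and folate cycle genes did not pass as a list, with 9 of 20 measured members higher, 11 lower, a median log2 fold change of -0.01 and a camera adjusted p of 0.814. Of the 20 members, 12 had a mean under 181 units, where a poor match of human probes to pig transcripts could hide a change. MAT1A, which encodes the main methionine adenosyltransferase of adult liver, averaged 138 ± 12.96 units in A and 138 ± 0.821 in C. GNMT (0.01, SE 0.17), PEMT (-0.04, SE 0.14), BHMT (-0.02, SE 0.11) and CBS (-0.09, SE 0.10) had log2 fold changes within their standard errors, and their group means lay between 117 and 151 units. MAT2A had a log2 fold change of 0.36 (SE 0.21) at its brighter probe set and -0.02 at the other. AHCYL1 (-0.16, SE 0.08) and FPGS (-0.28, SE 0.16) had the smallest unadjusted p of the list and did not pass. AHCY and MTR did not reach the intensity filter. Of 8 measured genes of DNA methylation and methyltransferases, 4 were higher and 4 lower (camera adjusted p 0.938, median log2 fold change -0.01, mean 0.02). SUV39H1 (-0.22, SE 0.09) and PRMT1 (0.43, SE 0.20) had the smallest unadjusted p there.

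Lipid genes did not pass as lists. In fatty acid and triglyceride synthesis, 7 of 16 measured members were higher (camera adjusted p 0.938), and the median log2 fold change of -0.02 differed in sign from the mean of 0.02. ELOVL6, a fatty acid elongase, averaged 333 ± 48.6 units in A against 189 ± 22.2 in C (log2 fold change 0.77, SE 0.13) and was the 1 member higher when adjusted over the list alone. FASN had log2 fold changes of 0.41 (SE 0.14) and 0.06 at its probe sets, SCD 0.04 (SE 0.09) at its brightest and 0.76 (SE 0.34) at another, and SREBF1 -0.06 (SE 0.10). In cholesterol synthesis and uptake, 7 of 11 members were lower (median -0.08, camera adjusted p 0.287). TM7SF2, a sterol reductase, averaged 468 ± 72.9 against 852 ± 144 (log2 fold change -0.84, SE 0.15) and was the 1 member lower when adjusted over the list alone, and DHCR7 had log2 fold changes of -0.39 (SE 0.13) and -0.09 at its probe sets. In fatty acid oxidation and ketone synthesis, 11 of 19 members were higher (median 0.07, camera adjusted p 0.918). Adjusted over the list alone, ADIPOR2 (0.36, SE 0.09) and FABP1 (0.54, SE 0.14) were higher and HSD17B4 (-0.44, SE 0.12) was lower. CPT1A and PPARA did not reach the intensity filter. None of the lipid genes passed over all probe sets tested.

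For alcohol metabolism, 4 of 8 measured members were higher and 4 lower (median 0.03, camera adjusted p 0.938). ADH1B averaged 143 ± 30.5 units in A against 103 ± 14.3 in C (log2 fold change 0.41, SE 0.15), and ALDH2, the mitochondrial aldehyde dehydrogenase, averaged 157 ± 21.9 against 200.2 ± 7.85 (-0.33, SE 0.11); neither passed. CYP2E1, an ethanol-oxidising cytochrome P450, averaged 521 ± 228 against 406 ± 437 (0.74, SE 0.64), with 910 units on C75 alone and a log2 fold change between 0.23 (without C64) and 1.56 (without C75) when 1 array was left out. In drug metabolism, 8 of 12 members were lower (camera adjusted p 0.588), and the median log2 fold change of -0.04 differed in sign from the mean of 0.05. CYP3A4 at its brightest probe set (-0.83, SE 0.16) was the 1 member lower when adjusted over the list alone, and CYP3A5 had a log2 fold change of -0.28 (SE 0.12). The third CYP3A4 probe set had a log2 fold change of 0.06. In glutathione and oxidative stress, 14 of 20 members were lower (median -0.10, camera adjusted p 0.287), with GSR at -0.47 (SE 0.15) and the metallothionein MT2A at -0.37 (SE 0.16). The fry test gave this list an adjusted p of 0.109, the smallest of any list and equal to that of the ribosomal list. With an estimated correlation its camera adjusted p was 0.684. In urea cycle and amino acid catabolism, 10 of 16 were lower (median -0.09, camera adjusted p 0.287), with OTC at -0.31 (SE 0.12) and AGXT at 0.45 (SE 0.20). Of the bile acid genes only 4 were measured, too few for the list test. The transporter ABCB4 (0.44, SE 0.15) and CYP27A1 (-0.26, SE 0.09) passed only when adjusted over those 4, which corrects for little. Over all probe sets their limma adjusted p was 0.537 and 0.512, so neither passed.

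Inflammation, secreted liver proteins and stress genes did not pass as lists. Of 9 measured interferon response genes, all with a mean under 181 units, 5 were higher (median 0.03, mean 0.17, camera adjusted p 0.329). ISG15 and the immunoproteasome gene PSMB8 (0.47, SE 0.09) were higher when adjusted over the list alone. For cytokines and inflammation, 8 of 13 members were lower (median -0.05, camera adjusted p 0.814), with TGFB1 at 0.32 (SE 0.16), CCL5 at -0.23 (SE 0.12) and TNF at -0.08 (SE 0.10). Among acute phase proteins, 10 of 19 were lower (median -0.02, camera adjusted p 0.814). TTR, which encodes transthyretin, averaged 1226 ± 68.7 units in A against 1544 ± 99.7 in C (-0.33, SE 0.09), and HPX averaged 599 ± 44.4 against 734 ± 15.1 (-0.29, SE 0.09; -0.06 at its dimmer probe set). Proteasome genes (14 of 26 higher, camera adjusted p 0.876), heat shock proteins (7 of 12 higher, 0.938), cell cycle genes (11 of 18 higher, 0.638) and apoptosis genes (8 of 16 higher, 0.638) did not pass. Proteasome and heat shock medians of 0.00 and 0.04 differed in sign from their means of -0.02 and -0.01. The smallest unadjusted p in these lists belonged to PSMD11 (-0.40, SE 0.23; 0.02 at its dimmer probe set), PSMC1 (-0.23, SE 0.14), DNAJB4 (-0.36, SE 0.13), DNAJA1 (0.44, SE 0.23), CDK1 (0.40, SE 0.11), CDKN1A (0.32, SE 0.12), CASP6 (-0.62, SE 0.24) and FAS (-0.18, SE 0.10). CASP6 passed over all probe sets without A63 (limma adjusted p 0.0214, between 0.0214 and 0.999 over the alternatives).

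Markers of liver cell types did not separate the groups as lists. Hepatocyte markers (7 of 13 lower, camera adjusted p 0.814) had a median log2 fold change of -0.08 and a mean of 0.01, with TF at -0.22 (SE 0.12) and, at its dimmer probe set, -0.47 (SE 0.10). The ALB probe set averaged 156 ± 58.4 units in A against 166 ± 14.7 in C. Kupffer cell and macrophage markers had a median of -0.04 but a mean of 0.13 (camera adjusted p 0.565). CYBB, a subunit of the phagocyte NADPH oxidase, averaged 184 ± 67.6 against 80.6 ± 16.4 (1.02, SE 0.22), the 1 marker higher when adjusted over the list alone, and TYROBP had a log2 fold change of 0.54 (SE 0.21). Lymphocyte markers (7 of 15 higher, camera adjusted p 0.814) had a median of -0.01 and a mean of 0.03, with CD79A at 0.35 (SE 0.16) and MS4A1 at -0.18 (SE 0.10). Neutrophil markers (4 of 6 lower, adjusted p 0.588) included FPR1 at -0.23 (SE 0.09) and MMP9 at -0.14 (SE 0.10). Endothelial markers (5 of 7 higher, adjusted p 0.814) included ENG at 0.13 (SE 0.11; -0.08 at its dimmer probe set) and STAB1 at -0.06 (SE 0.09; -0.44, SE 0.15, at its dimmer probe set). Erythroid markers (5 of 8 lower, adjusted p 0.814) included HBB at -0.35 (SE 0.17) and EPB42 at 0.15 (SE 0.11). Matrix and stellate cell markers (12 of 19 lower, adjusted p 0.814) included THY1 at 0.25 (SE 0.12; -0.07 at its dimmer probe set), TIMP2 at 0.19 (SE 0.11) and COL1A1 at -0.09 (SE 0.13; 0.11 at its dimmer probe set). Of the bile duct markers 4 were measured, too few for the list test, and 3 of them were higher. SPP1 did not reach the intensity filter.

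The Affymetrix control probe sets set A63 apart, and at GAPDH and 18S rRNA all A arrays lay above all C arrays. On A63 the bacterial transcripts bioB, bioC, bioD and cre were brighter than the median of the other 5 arrays by ratios of 2.61, 2.55, 2.38 and 1.84. The GAPDH control probe sets had median ratios of 1.33 to 1.46 on the A arrays and 0.602 to 0.820 on the C arrays. The 18S rRNA probe sets had median ratios of 1.08 to 1.85 on the A arrays, the highest on A63, and 0.822 to 0.928 on the C arrays. The 28S rRNA and beta-actin probe sets did not separate the groups: 28S ratios were 0.941 to 1.402 in A and 0.814 to 1.08 in C, and beta-actin ratios 0.708 to 1.28 in A and 0.890 to 1.57 in C. The 3' to 5' ratio of GAPDH lay between 0.744 and 1.104 on the A arrays and between 0.768 and 1.04 on the C arrays. For beta-actin it lay between 0.148 and 0.313 on the A arrays and between 0.120 and 0.218 on the C arrays.

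**Figure D3:**
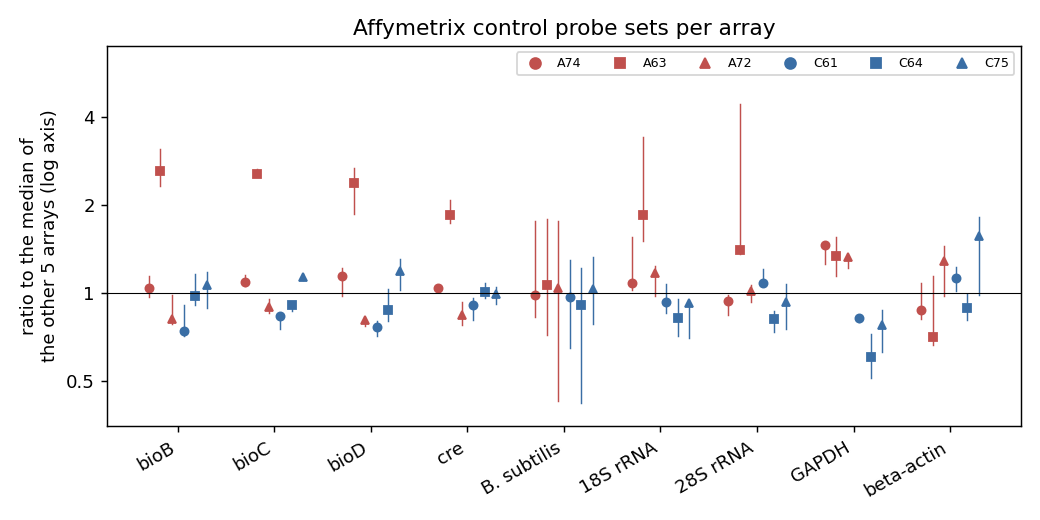
Ratio of each array's Affymetrix control probe sets to the median of the other 5 arrays, on a log axis, with symbols for the median over the probe sets of a control and lines for their range. Red symbols are A arrays and blue symbols C arrays. The red squares of A63 stood at 2.61 for bioB and 1.84 for cre, and the GAPDH ratios of the A arrays all lay above those of the C arrays.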

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

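The test of the added control transcripts was chosen after their values had been seen. On A63 the bacterial transcripts that are usually added before hybridisation stood above the other 5 arrays, from a median ratio of 1.84 for cre to 2.61 for bioB, a signal outside the pig measurement. The B. subtilis probe sets had a ratio of 1.065. Less pig cRNA relative to the added transcripts could give such values, but the ratios, 1.84 or more, had been seen before a bound was set, so the test could not decide and the cause stays open. No biological explanation was tested for the controls. How A63 bears on the group comparison was measured only by leaving it out: 19 probe sets passed the adjusted threshold without A63, against 3 with it. The count at an unadjusted limma p under 0.05 went the other way, with 670 without A63 against 782 with it.

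On the array in no group, 56.55% of the 10017 tested probe sets lay outside the range of the 6 compared arrays. An array exchangeable with those 6 would give 28.57%. But the probe sets were selected by their intensity on the 6 arrays, and this array was not scaled to them. It read 909 probe sets over 2-fold lower than the mean of the 6 arrays and 161 over 2-fold higher. The comparison with 28.57% therefore cannot tell a difference in kind from selection or scaling. Groups of 3 arrays are too small for an outlier test within a group, so none was run.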

How the results depend on the processing

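The filter of 200 was chosen after the data were seen, and so was keeping, for left-out replicates, the probe sets tested on all 6 arrays, since the filter had first been applied to the remaining 5 arrays; the cause of the shifts was not tested except where stated. Of 3 probe sets past the adjusted threshold, array quality weights gave 22 (16 higher, 6 lower) and probe sets without a family suffix gave 1, NUCB2, since RPL36 and RPS19 have no such probe set. Leaving out 1 replicate gave between 2 and 19, with 19 without A63 and 14 without C75. With the filter on the remaining 5 arrays it gave between 0 and 14: 0 without A74 and 0 without A72, since NUCB2 and RPL36 then left the test, 14 without A63 and 12 without C75. NUCB2 and RPL36 passed in each of the 21 and 20 alternatives that tested them. Of 33 probe sets under the 2-fold rule, a pseudocount of 64 gave 21 and probe sets without a family suffix gave 6. Left-out replicates gave between 28 and 56, or between 26 and 55 with the filter on the remaining 5 arrays, the highest without C75 in both. Of 3 lists, probe sets without a family suffix gave 1 (ribosomal proteins), and camera with an estimated correlation and fry each gave 0; at an unadjusted p under 0.05 these gave 2 and 3. Left-out replicates gave between 1 and 3 lists in both versions, with 1, ribosomal proteins, without A74. The ribosomal list passed in 24 of 26 alternatives, the respiratory chain in 21 and glucose metabolism in 13. Of 52 named probe sets with a log2 fold change of at least 0.3 in size, 0 changed sign under any alternative. Many of them were named for groups without overlap or for the smallest p, so a change of sign was unlikely from the start. Other scalings moved the median log2 fold change of all probe sets to between -0.02 and -0.01. No paired analysis was possible because A and C share no replicate numbers. Signal over background limits the rest: 69.3% of the tested probe sets had a mean under 181 units, 2 times the array median.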

Other observations

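The list of secretory pathway genes was drawn up after MANF, PPIB, SEC61B and NUCB2 had been seen to be higher in A, and it leaves these 4 out. Genes of protein translocation, glycosylation and transport in the early secretory pathway tended upward in A. Of 60 list members 36 were measured, with 25 higher, 11 lower and a median log2 fold change of 0.12. SSR2, a subunit of the translocon-associated complex, averaged 812 ± 69.4 units in A against 561 ± 34.4 in C (log2 fold change 0.52, SE 0.10, n = 3 each), and SSR4 of the same complex had a log2 fold change of 0.56 (SE 0.14). FKBP2 (0.63, SE 0.14), DDOST (0.43, SE 0.10) and FKBP11 (0.52, SE 0.14) were also higher with no overlap, while SEC61A1 (-0.30, SE 0.11) and SEC61A2 (-0.21, SE 0.08) were lower. None passed the limma adjusted threshold. The hypothesis that these genes were higher as a set was tested against 10000 lists matched on intensity: the list's median stood at percentile 99.99 of them. The unadjusted camera p was 0.000302, and with an estimated correlation it was 0.114, so the set may stand out only if its members vary independently.

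All 4 tests of the ribosomal protein list were chosen after its rise had been seen. Leaving out A63 gave a median log2 fold change of 0.40, against 0.32 with it. A63 had the lowest mean deviation of the A arrays, 0.07 against 0.18 on A74 and 0.24 on A72. The rise therefore did not rest on A63, but its omission was bound to raise the difference and was no separate test. Over all alternatives, with each replicate left out among them, the median lay between 0.26 and 0.40. A general shift of bright probe sets is argued against by a median at percentile 100 of 10000 lists matched on intensity. The 9 members without a family suffix had a median of 0.28, with 8 of 9 higher. That suffix was set for human transcripts and the match to pig transcripts was not checked. The test therefore cannot decide whether probe sets read several pig family members. What also stays open is that members swing together between samples whatever the group. Their median correlation after removal of group means was 0.26, above the bound of 0.10 from matched lists. So 3 samples against 3 could differ by chance in 1 shared factor, and a biological difference was not tested apart from it.

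All 3 tests of the lower CYP3A probe sets were chosen after their values had been seen. Leaving out A63 gave a median log2 fold change of -1.07, against -0.95 with all arrays. A63 read highest of the A arrays at the 4 CYP3A4 and CYP3A43 probe sets that were lower in A. The drop therefore did not rest on A63, but its omission could only deepen the drop of these 4 and was no separate test. If 1 pig transcript were read by several human CYP3A probe sets, they should rise and fall together within groups. Over all 6 probe sets the median correlation between genes was 0.0566, at percentile 63 of matched probe sets and below their bound of 0.46. Most pairs between genes involved 1 of 2 probe sets with means under 181 units. These were the CYP3A5 probe set (94.2 in A, 117 in C) and a CYP3A4 probe set (152 in A, 145 in C). Low signal could weaken such pairs, so the value was left undecided. Over the 4 CYP3A4 and CYP3A43 probe sets with a C mean over 181 units, the median correlation was 0.90, above the bound of 0.55 from matched probe sets. They were picked by their brightness in C, where they were high, which left out the CYP3A4 probe set that did not fall. These 4 moved together within groups and may be readings of a shared pig signal and not 4 separate observations, but a subset picked this way cannot decide it.

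The splits were chosen before the results were seen. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3 probe sets past the adjusted threshold, and the highest of the others gave 0; 1 of the 10 splits, the real one, gave as many. For the 2-fold rule the real split gave 33 and the highest other 20, and again 1 split gave as many. For gene lists the real split gave 3 and the highest other 5, and 4 of the 10 splits, the real one and the 3 that put A74 and A72 with 1 C array, gave as many.

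The array in no group had a median of 83.5 units, and 39.1% of its probe sets reached 100. Its Pearson r with the compared arrays lay between 0.775 and 0.796 over all probe sets. NUCB2 read 19.9 units on it, RPL36 60.0, RPS19 1148, IFITM3 160.0, CYP3A43 2143, SOCS2 110.8 and TM7SF2 101.6. Of these, NUCB2, RPL36, IFITM3 and CYP3A43 lay nearer to the C means, and RPS19, SOCS2 and TM7SF2 nearer to the A means. No group was inferred from these values.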
